A study of Mus musculus with 16 samples.

How the data were processed

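The series holds RNA sequencing of primary mouse lung fibroblasts and of unseparated lung cells, from wild-type (WT) mice or mice labelled as deficient in ST2, the IL-33 receptor encoded by Il1rl1 (KO). Cells were infected with an adenovirus coding for full-length IL-33 (FL), mature IL-33 (M) or nothing (NULL), and RNA was taken 72 h later. The 2 deposited tables hold the same values: of 434648 cells compared, 2 were not identical, and the largest relative difference was 6.5e-15. The columns carry the titles of the fibroblast samples, so the values were read as 8 fibroblast libraries: 2 NULL, 1 FL and 1 M library per genotype. The labels assign 1 of the 2 identical tables to the unseparated cells, so the cell type rests on the column titles alone, and unseparated cells as the source of the values are not excluded. The unseparated lung cells, and the comparison of the cell types, were not analysed here.

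The deposited unit is signal: normalized counts per gene, which per the labels came from Salmon and DESeq2 on GRCm38.p6, with no versions given in the sources used here. The table lists 54331 genes, 30284 of them above 0 in at least 1 library. Normalized totals were 2.39e+07 to 2.92e+07 per library, and 22193 to 23645 genes were above 0. The smallest step between low values (up to 12) put 1 read at 0.707 to 1.18 normalized counts and the depth at about 2.37e+07 to 3.97e+07 reads. Within a tolerance of 0.02 steps, 59.9% to 71.3% of low values were whole multiples of the step, so whole reads were not recovered and the tests that need them were not run.

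Values were taken to log2 after adding 1. Genes with a mean of at least 10 over the 8 libraries were tested (15527 genes, with 99.9% of each library's total). Among the tested genes, 12 symbols occur more than once and 10 genes have no symbol. The main test was limma-trend (limma 3.58.1, R 4.3.3; two-sided, Benjamini-Hochberg adjustment within each comparison, adjusted p below 0.05). It fitted 4 group means, genotype by NULL or IL-33, with FL and M as the 2 samples of IL-33 (4 residual and 2.82 prior degrees of freedom). The spread in this fit therefore includes the difference between the isoforms. From it came the IL-33 effect in WT, in KO and averaged, the difference of these effects, the KO effect averaged and in NULL virus, and KO with IL-33 against WT with NULL. FL against M came from an additive model of genotype and infection (prior degrees of freedom 2.94). These choices, the gene lists and the rule for naming genes were fixed before the data were examined.

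After the data were seen, each IL-33 library was also compared with the NULL pair of its genotype in a fit of 6 groups (2 residual and 4.78 prior degrees of freedom), which assumes that a lone library varies like the NULL pairs. Nothing in the labels says whether the NULL libraries came from separate cultures or animals. The p-values measure only the spread between these samples, which may be technical. The NULL libraries of a genotype were not copies of each other, with a median squared difference 2.28 (KO) and 3.45 (WT) times that of counting noise.

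Of 37 gene lists, 33 had at least 3 measured genes and were tested with camera (preset correlation 0.01), with camera using an estimated correlation and with fry as alternatives. With the preset correlation, the number of lists called ran from 6 (IL-33 in KO) to 14 (IL-33 in WT). Each list was also counted gene by gene, over all tested genes and adjusted over the list alone. Named genes were Il33 and Il1rl1, then the 10 largest fitted rises and falls in the averaged comparisons and 5 in the others, among genes past the threshold with a mean of at least 50. In the averaged comparisons the effect also had to have the same sign in each genotype (IL-33) or with each insert (KO). Genes named for their p alone did not have to meet this sign rule. Where fewer than 3 passed in a direction, the 3 with the smallest p were named, and from each list up to 4 members with the smallest p. Predicted gene models were counted and left unnamed except where stated.

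Alternatives were an added 0.5 or 8, no filter or a mean of at least 50, TMM factors, quantile normalization, 6 groups, the number of the NULL libraries as a replicate block, and leaving out each library in turn. Gene positions came from the GENCODE annotation of GRCm38. On simulated data with 200 changed genes among 15527 and the spread of the 4 groups, the IL-33 test in WT and the averaged KO test recovered 56% and 77% of changes of 2-fold and 90% and 95% of those of 4-fold, with 5 and 9 unchanged genes called. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.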

Results

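Il33, the transcript that the vectors carried, and Il1rl1, the gene of the IL-33 receptor ST2, were read first in the 8 libraries titled as lung fibroblasts. The Il33 level was 193 and 201 normalized counts in the wild-type (WT) NULL libraries and 216 and 214 in the NULL libraries labelled ST2 knockout (KO). It reached 593840 in the WT library with full-length IL-33 (FL) and 248956 in the WT library with mature IL-33 (M). In the KO libraries it was 1080220 with FL and 81110 with M, so the amount of Il33 transcript was not matched between vectors or genotypes. Il33 made up 2.12% and 1.04% of all normalized counts in the WT FL and WT M libraries and 3.70% and 0.292% in the KO FL and KO M libraries.

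Il1rl1 was near the low end of the measured range in all 8 libraries. It stood at 18.3 and 106 normalized counts in the WT NULL pair (mean 62.2, SD 62.2, n = 2) and at 73.1 and 69.2 in the KO NULL pair (mean 71.2, SD 2.75, n = 2). The FL and M libraries held 33.9 and 70.7 in WT and 79.2 and 85.2 in KO. The fitted KO effect on Il1rl1, averaged over inserts, was a log2 change of 0.70 (SE 0.53, limma adjusted p = 0.4372). A total per gene does not show whether an exon is missing, so the genotype was taken from the labels.

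Genotype and the WT M library set the largest differences between samples. On the first principal component (35.9% of variance) the 4 KO libraries lay together, at -37.0 to -29.1, and the WT M library lay at 59.6. On the second (33.6%) the WT NULL libraries lay at -44.1 and -47.0, the WT FL library at -15.4 and the WT M library at 67.7. Of 12559 genes compared, 63 differed by more than 2-fold within the WT NULL pair, 51 within the KO NULL pair and 96 between the KO FL and KO M libraries. Between the WT FL and WT M libraries 1344 did.

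**Figure D1:**
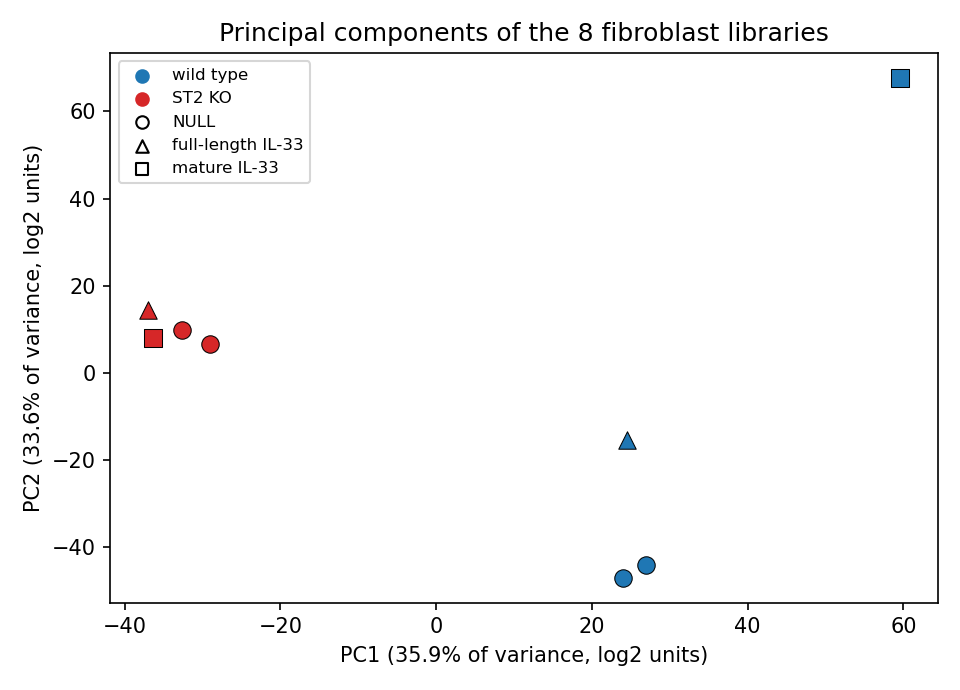
Principal components of the 8 fibroblast libraries, with colour for genotype and shape for the infecting virus. The percentages on the axes are shares of the variance.

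In WT fibroblasts, interferon-induced genes were higher in the 2 IL-33 libraries than in the NULL pair. The NULL libraries hold no vector transcript to measure, so IL-33 and a different virus dose cannot be told apart here. Oas2, an RNA sensor of the 2'-5' oligoadenylate synthetase family, rose 4.70-fold (log2 2.23, SE 0.14, adjusted p = 0.0044; limma, 2 IL-33 against 2 NULL libraries). Zbp1, a sensor of nucleic acids, rose 4.16-fold (log2 2.06, SE 0.14, adjusted p = 0.0044) and Ly6a (Sca-1), a surface marker induced by interferon, 3.94-fold (log2 1.98, SE 0.15, adjusted p = 0.0073). Irf7, a transcription factor of the type I interferon response, rose from a mean of 1027 (SD 40.3, n = 2) to 2516 normalized counts (SD 506, n = 2; log2 1.28, adjusted p = 0.0339). Il33 itself rose by a log2 of 10.92 (SE 1.07, adjusted p = 0.0156) and the adhesion receptor gene Adgrg2 by 2.29 (SE 0.27, adjusted p = 0.0335).

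The largest falls under the naming rule in WT fibroblasts were those of Igfbp2, Ramp1, Popdc2, Bmp6 and Cspg4. Igfbp2, which binds insulin-like growth factors, fell from 24576 and 25864 normalized counts to 7233 (FL) and 3804 (M), 4.81-fold (log2 -2.27, SE 0.26, adjusted p = 0.0330). Ramp1, a coreceptor for calcitonin gene-related peptide, fell from 167 and 183 normalized counts to 44.5 and 41.4 (log2 -2.001, adjusted p = 0.0098), Popdc2 fell 2.54-fold (adjusted p = 0.0088), Bmp6 2.25-fold (adjusted p = 0.0463) and Cspg4, the pericyte proteoglycan NG2, 2.11-fold (adjusted p = 0.0088). In all, 28 genes rose and 13 fell among 15527 tested, 23 and 7 of them by at least 2-fold. Without the WT FL or the WT M library, the effect rested on the 1 IL-33 library left in WT. The difference between these 2 libraries then also left the measure of spread, and the count of 41 was far higher. It was 11 and 17 without the KO FL or KO M library, 8 without either KO NULL library, and 1 and 0 without WT NULL 1 or 2.

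Of 28 measured interferon response genes, 4 rose in WT fibroblasts and 0 fell (15 rose adjusted over the list alone; median log2 0.45; camera adjusted p = 9.71e-11, and adjusted p = 0.5291 with an estimated correlation). Cholesterol synthesis genes had a median of -0.51 over 17 members (0 passed the threshold; 13 fell adjusted over the list alone; camera adjusted p = 2.48e-07, adjusted p = 0.5291 with an estimated correlation). Genes of the contractile apparatus had a median of -0.65 over 11 members (0 passed; 10 fell adjusted over the list alone; camera adjusted p = 4.41e-05, adjusted p = 0.5330 with an estimated correlation). Smooth muscle and pericyte markers had a median of -0.98 over 9 members, 1 of which fell (4 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.5291 with an estimated correlation).

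Camera called 14 of 33 lists for IL-33 in WT fibroblasts, 5 upward and 9 downward, and 5 of these calls were lost without the WT M library. NF-kB dependent cytokines and chemokines had a median of 1.12 over 25 members (0 passed; camera adjusted p = 7.09e-06, adjusted p = 0.6487 with an estimated correlation), and macrophage and monocyte markers 0.61 over 15 (0 passed; camera adjusted p = 0.0010, adjusted p = 0.6487 with an estimated correlation). Collagens and extracellular matrix genes had a median of -0.43 over 26 members (0 passed; 2 fell adjusted over the list alone; camera adjusted p = 0.0012) and fibroblast markers -0.77 over 16 (0 passed; 1 fell adjusted over the list alone; camera adjusted p = 0.0071), both with adjusted p = 0.6578 with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.12 over 23 members (0 passed, also adjusted over the list alone; camera adjusted p = 0.0072, adjusted p = 0.6487 with an estimated correlation). Without the WT M library, adjusted p was 0.1338 for the NF-kB, 0.5378 for the macrophage, 0.5378 for the collagen and 0.8593 for the fibroblast list, and the ribosomal call was lost too (adjusted p = 0.0563). The collagen, fibroblast and ribosomal calls were also lost with quantile normalization, and the fibroblast call with a mean of at least 50.

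Set against the WT NULL pair alone, the WT FL library differed at 1148 genes (543 higher, 605 lower) and the WT M library at 7650 (3492 higher, 4158 lower). These counts come from a fit added after the data were seen, in which a lone library is assumed to vary like the NULL pairs. The interferon genes named above moved in both: Oas2 by a log2 of 2.31 (FL) and 2.16 (M), Zbp1 by 1.92 and 2.19, Ly6a by 1.92 and 2.03 and Irf7 by 1.07 and 1.48. They had passed a test whose spread includes the difference between FL and M. That choice favours genes with like values in both libraries. Of the 28 interferon response genes, 20 were higher with FL, and with M 16 were higher and 3 lower. Without KO NULL 1 or KO NULL 2, the count for the FL library was 438 or 441.

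Inflammatory genes were higher in the WT M library than in the WT NULL pair, with p-values that take their spread from the NULL pairs and no repeat of this library to test them on. Saa3, an acute phase protein gene, was at 5020 normalized counts against 29.4 and 67.8 in the WT NULL pair and 94.4 in the WT FL library (log2 6.78 against the NULL pair, adjusted p = 2.84e-05). The neutrophil chemokine gene Cxcl1 was at 731 against 13.1 and 18.3 (log2 5.47, adjusted p = 2.17e-05), the monocyte chemokine gene Ccl2 at 4542 against 554 and 609 (log2 2.96, adjusted p = 1.24e-06), and Arg1, which encodes arginase 1, at 3523 against 102 and 96.7 (log2 5.13, adjusted p = 9.26e-07). Of 25 NF-kB dependent genes, 24 were higher (median log2 2.45), against 2 in the WT FL library (median 0.18). These genes were chosen after their values were seen.

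The same library had more macrophage, mesothelial and keratin transcripts and fewer fibroblast transcripts. The complement gene C1qa was at 1955 normalized counts (831 to 895 in the other 7 libraries), the lysozyme gene Lyz2 at 35415 against 14733 and 15841 in the WT NULL pair, and the mesothelial gene Msln at 1055 against 171 and 175. Macrophage and monocyte markers had a median log2 change of 1.15 (14 of 15 higher) and mesothelial markers 1.83 (7 of 8 higher, 1 lower). Airway epithelial markers had a median of 1.82, with 4 of 5 higher: Krt8, Krt18, Krt19 and Cdh1, which other epithelia and mesothelium also express. Alveolar type 2 markers had a median of -1.61 (5 of 7 lower), close to the -1.74 of the WT FL library, where 0 of 7 passed. Lum, which encodes the matrix proteoglycan lumican, was at 90.6 against 929 and 1056 (log2 -3.44, adjusted p = 1.03e-06), Rgs5 at 147 against 3709 and 3820, and Pdgfrb at 5724 against 26124 and 26007. Of 26 collagen and matrix genes, 24 were lower (median -1.005), and of 16 fibroblast markers 14 were lower (median -1.35).

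In KO fibroblasts, 3 genes passed the threshold for IL-33 in the fit of 4 groups, and each is a marker of alveolar type 2 epithelium. Sftpc, which encodes surfactant protein C, was at 1.36 and 0 normalized counts in the KO NULL pair and at 162 and 156 with FL and M (adjusted p = 0.0106). Sftpb was at 0 and 0.639 against 55.8 and 57.3 (adjusted p = 0.0106). Slc34a2, a phosphate transporter gene, was listed at 0 in both KO NULL libraries and at 24.4 and 27.6 with IL-33. Their fitted log2 changes (6.70 for Sftpc, 5.49 for Sftpb) depend on the 1 added before taking logs. Il33 itself was higher in both KO IL-33 libraries but did not pass (log2 10.42, SE 1.07, adjusted p = 0.1163). Trim2 (log2 0.60) and Greb1 (1.26) were next among rises, and Igfbp3 (-0.58, adjusted p = 0.5275), C4b (-0.74) and Gbp3 (-0.50) were the falls with the smallest p, none past the threshold.

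The count of 3 for IL-33 in KO fibroblasts was 27 with the spread taken from the NULL pairs alone (6 groups). It was 0 without the KO FL library and 1 without the KO M library. Leaving out the WT FL or WT M library gave 8 and 6, and either WT NULL library 0. The alveolar type 2 list (7 measured) had 3 members higher and 0 lower (4 higher adjusted over the list alone; camera adjusted p = 3.12e-14, and adjusted p = 0.0411 with an estimated correlation), which was the one list call in any comparison that held with the estimated correlation. The interferon response list did not rise in KO: 0 of 28 members passed, also adjusted over the list alone, and the median was -0.23 (camera down, adjusted p = 1.15e-12, adjusted p = 0.6071 with an estimated correlation). NF-kB dependent genes had a median of -0.03 (camera adjusted p = 0.7242).

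Against the KO NULL pair alone, the KO FL library differed at 37 genes (11 higher, 26 lower) and the KO M library at 5. These counts assume that a lone library varies like the NULL pairs. In the KO FL library the 28 interferon genes had a median log2 change of -0.33, with Ifit3 at -0.95 and Irf7 at -0.52. Hspa1a, an inducible chaperone gene, stood at 2.04. In the KO M library Il33, Sftpc, Sftpb and Slc34a2 were higher and the predicted gene Gm6741 was lower. With no filter on low values the counts were 732 and 814, with 2 of the 5 genes of the KO M library kept. The count of 37 was 6 without KO NULL 1, 15 without KO NULL 2 or WT NULL 1, and 14 without WT NULL 2. The count of 5 was 1 without either WT NULL library and 3 with a mean of at least 50.

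The IL-33 effect itself differed between the genotypes at 20 genes, 14 with a smaller and 6 with a larger value in KO. For Ly6a the KO effect minus the WT effect was -2.58 on the log2 scale (SE 0.21, adjusted p = 0.0124), for Zbp1 -2.39 (SE 0.20, adjusted p = 0.0124), for Oas2 -2.35 (SE 0.20, adjusted p = 0.0138), for the complement gene C4b -2.08 (SE 0.19, adjusted p = 0.0158) and for Igfbp3 -1.72 (SE 0.11, adjusted p = 0.0077). In the other direction were Sftpc (8.92, adjusted p = 0.0077) and Sftpb (7.17, adjusted p = 0.0077), both near 0 in the KO NULL pair, then Ramp1 (2.18, SE 0.24, adjusted p = 0.0420), Popdc2 (1.38, SE 0.15, adjusted p = 0.0450) and Cspg4 (1.26, SE 0.12, adjusted p = 0.0245). At 13 of the 20 genes, the level in WT was higher with IL-33, the KO NULL level was above the WT NULL level and the difference was negative. These comparisons share NULL libraries, which builds in part of that pattern, and the number that sharing alone would give was not computed.

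Ly6a shows the levels behind this: 93.4 and 113 normalized counts in WT NULL, 393 and 422 in WT with FL and M, 884 and 844 in KO NULL, and 514 and 630 in KO with FL and M. Of 28 interferon genes, 2 had a smaller IL-33 effect in KO and 0 a larger one (15 smaller adjusted over the list alone; median -0.70; camera adjusted p = 1.71e-18, adjusted p = 0.3223 with an estimated correlation). The count of 20 was 5604 without the WT FL library and 489 without the WT M library. It was 0 without the KO FL, KO M or WT NULL 2 library, 1 without WT NULL 1, and 2 and 3 without KO NULL 1 or 2.

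Averaged over genotypes, 5 genes differed between the IL-33 and NULL libraries, all higher with IL-33: Il33 (log2 10.67, SE 0.76, adjusted p = 0.0317), Ly6e (0.58, SE 0.05, adjusted p = 0.0453), an interferon-induced surface protein gene, and 3 predicted genes named after their values were seen, Gm36569 (3.73, adjusted p = 0.0317), Gm45090 (3.31, adjusted p = 0.0453) and Gm2223 (3.02, adjusted p = 0.0453). Gm36569 (an antisense RNA) and Gm2223 (a processed pseudogene) were listed at 0 in both WT NULL libraries, so their fitted changes depend on the added 1, and whether their reads belong to other transcripts of the same sequence was not tested. Apart from Il33, these rises were in WT: the IL-33 effect on Ly6e was 1.34 in WT and -0.175 in KO, on Gm2223 6.75 and -0.71, on Gm36569 7.04 and 0.43 and on Gm45090 6.17 and 0.45, and for these 4 genes the effects differed between the genotypes (adjusted p = 0.0077, 0.0077, 0.0138 and 0.0392). In KO NULL they already stood above WT NULL, by a log2 of 2.33 for Ly6e, 7.36 for Gm2223, 7.80 for Gm36569 and 5.61 for Gm45090. Why the WT NULL pair was low in these genes was not tested. The rises next in rank did not pass: Oas2 (1.06, adjusted p = 0.0506), Slfn5 (0.62, adjusted p = 0.0806) and Zbp1 (0.86, adjusted p = 0.0934). Neither did any fall, the first in rank being Popdc2 (-0.65, adjusted p = 0.0979), the taurine transporter gene Slc6a6 (-0.52, adjusted p = 0.1047) and Ramp1 (-0.91, adjusted p = 0.1328).

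The averaged IL-33 count of 5 was 6238 without the WT FL library and 801 without the WT M library. It was 1 without the KO FL or WT NULL 1 library, 2 without KO M, and 0 without KO NULL 1, KO NULL 2 or WT NULL 2. Cholesterol synthesis genes had a median of -0.29 (0 of 17 passed; 6 fell adjusted over the list alone; camera adjusted p = 1.30e-07, adjusted p = 0.5461 with an estimated correlation). Interferon response genes had a median of 0.06 (0 of 28 passed; 4 rose adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.5461 with an estimated correlation). Without the WT FL library, that interferon call was lost (adjusted p = 0.1966).

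**Figure D2:**
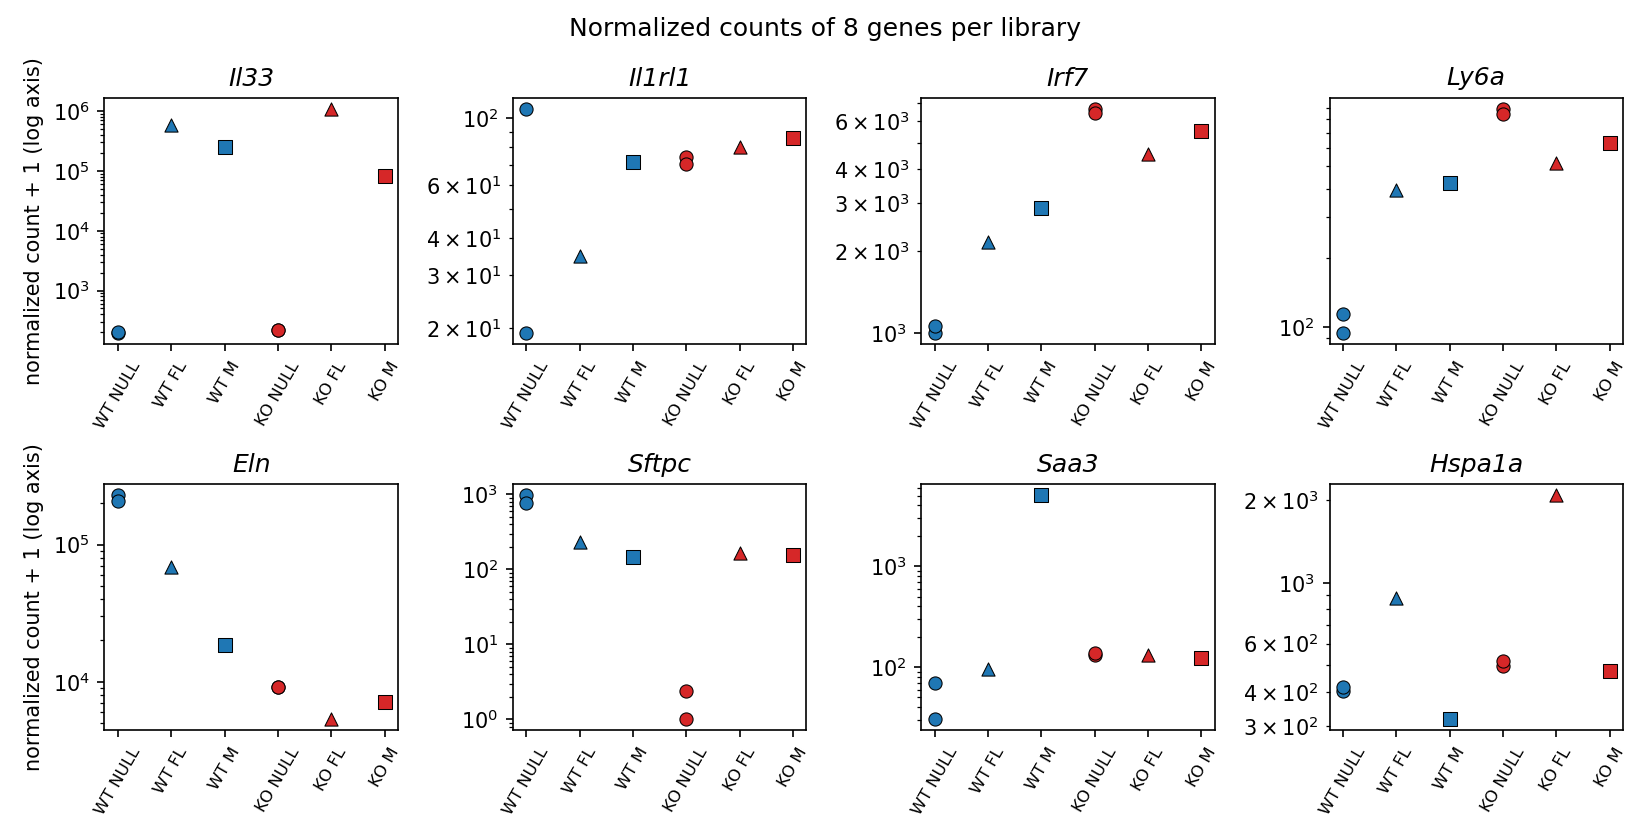
Normalized counts plus 1, on a log axis, of Il33, Il1rl1 and 6 genes of the main responses in each fibroblast library.

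Averaged over inserts, 1853 genes differed between KO and WT fibroblasts, 1065 higher and 788 lower in KO (290 and 229 by at least 2-fold; 4 libraries against 4). Hormad1, a gene of meiotic chromosome axes, was at 1276 to 1434 normalized counts in the KO libraries and at 0 to 2.15 in the WT libraries (fitted log2 9.79, dependent on the added 1; adjusted p = 9.48e-05). Epyc, a matrix proteoglycan gene, was higher 24.6-fold (log2 4.62, SE 0.30, adjusted p = 5.17e-04), as were Cux2 (13.1-fold), the myostatin gene Mstn (12.9-fold), Zfp965 (12.9-fold), the matrix protein gene Dpt (11.1-fold), the repressor gene Zhx2 (8.85-fold), the chloride channel gene Ano1 (8.53-fold), Kif24 (7.86-fold) and the deiodinase gene Dio2 (7.32-fold), with adjusted p from 6.02e-04 to 0.0253.

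Eln, which encodes elastin, was lower in KO by 11.8-fold (log2 -3.56, SE 0.38, adjusted p = 0.0027). Its levels were 228091 and 208660 normalized counts in WT NULL, 68999 in WT FL and 18425 in WT M, against 5323 to 9151 in the 4 KO libraries. Sult4a1, a sulfotransferase gene, was 14.8-fold lower (log2 -3.89, SE 0.16, adjusted p = 9.48e-05). Also lower were Sftpc (25.5-fold, with the KO NULL pair near 0), the receptor gene Erbb4 (16.9-fold), the pericyte gene Rgs5 (13.4-fold), the keratin genes Krt7 (11.2-fold) and Krt8 (10.2-fold), the glutathione transferase gene Gsta3 (10.6-fold), Syt10 (10.2-fold) and the endothelial adhesion gene Esam (10.2-fold), with adjusted p from 5.17e-04 to 0.0213.

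Of 28 interferon response genes, 22 were higher in KO and 0 lower (25 higher adjusted over the list alone; median log2 0.86; camera adjusted p = 7.74e-20, adjusted p = 0.5283 with an estimated correlation). Zbp1 was 5.21-fold higher (log2 2.38, SE 0.10, adjusted p = 9.48e-05), Irf7 3.58-fold (log2 1.84, SE 0.11, adjusted p = 3.16e-04), Oas2 by a log2 of 1.80 (adjusted p = 2.84e-04) and the guanylate-binding protein gene Gbp2 by 1.19 (adjusted p = 1.30e-04). Of 11 contractile genes, 5 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.57; camera adjusted p = 1.95e-04, adjusted p = 0.6862 with an estimated correlation): Actg2 rose by a log2 of 1.33 (adjusted p = 0.0021), Cnn1 by 0.83 (adjusted p = 0.0013) and Acta2 by 0.72 (adjusted p = 0.0173), while Des, which encodes desmin, fell by 1.53 (adjusted p = 0.0201). Most of this list's shift lay in the WT libraries with IL-33, at medians of -0.42 (FL) and -0.87 (M) from the WT NULL mean. In NULL virus the median was 0.18, with 1 of 11 genes higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.1009).

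Mitochondrially encoded transcripts were lower in KO at 6 of 13 members (12 adjusted over the list alone; median -0.27; camera adjusted p = 4.35e-07, adjusted p = 0.5283 with an estimated correlation), mt-Nd5 by a log2 of -0.47 (adjusted p = 0.0044). Mesothelial markers were lower at 4 of 8 (5 adjusted over the list alone; median -1.83; camera adjusted p = 0.0041, adjusted p = 0.6862 with an estimated correlation), and endothelial markers at 3 of 12 (5 adjusted over the list alone; median -0.72; camera adjusted p = 0.0394, adjusted p = 0.6862 with an estimated correlation). Emcn (log2 -2.27), Pecam1 (-1.99) and Cdh5 (-2.38) were the endothelial genes. Nr4a1, an immediate early gene of the nuclear receptor family, was higher by 1.93 (SE 0.07, adjusted p = 5.25e-05). The WT mean in these contrasts includes the WT M library, with high mesothelial and low endothelial transcripts. The endothelial call was kept without that library. It was lost without the WT FL or WT NULL 1 library, with a mean of at least 50, with quantile normalization and with 6 groups (adjusted p up to 0.4789).

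The count of 1853 was 5944 without the WT FL library and 6161 without the WT M library. It was 595 and 644 without the KO FL or KO M library, 552 without either KO NULL library, and 596 and 643 without WT NULL 1 or 2. Cux2, Rgs5, Krt8, Syt10, Acta2 and Des were not past the threshold when any 1 of the 4 KO or 2 WT NULL libraries was left out. The same held for Krt7 except without KO NULL 2 and for Cdh5 except without KO NULL 1, where both kept their calls. Hormad1, Epyc, Sult4a1, Eln, Zbp1 and Irf7 were past it without each of the 8 libraries.

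In cells with NULL virus the KO libraries already had high interferon genes. Zbp1 was 11.9-fold higher than in WT NULL (log2 3.58, SE 0.14, adjusted p = 1.49e-04), Oas2 7.86-fold (log2 2.97, SE 0.14, adjusted p = 2.89e-04) and Irf7 6.37-fold (means 6545, SD 137, against 1027, SD 40.3, n = 2 each; adjusted p = 4.35e-04). Of 28 interferon genes, 19 were higher and 0 lower (25 higher adjusted over the list alone; median 1.29; camera adjusted p = 3.57e-26, adjusted p = 0.1791 with an estimated correlation). Also higher were Hormad1, Epyc (26.9-fold), Zfp965 (15.0-fold), the complement factor gene Cfb (14.6-fold) and the stromelysin gene Mmp3 (13.6-fold). Eln was 23.9-fold lower, Sult4a1 13.7-fold and Cdh5, which encodes VE-cadherin, 10.9-fold, and Sftpc and Sftpb were near 0 in KO.

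In NULL virus 664 genes differed (400 higher, 264 lower in KO; 228 and 114 by at least 2-fold). The count was 4998 and 4996 without the WT FL or WT M library. It was 276 and 278 without KO FL or KO M, 70 and 82 without KO NULL 1 or 2, and 85 and 103 without WT NULL 1 or 2. Mmp3 and Cdh5 lost their calls without any 1 of the 4 NULL libraries and without KO FL or KO M, and Zfp965 in the same omissions except that of WT NULL 2. Eln lost its call without any 1 of the NULL libraries, Cfb without KO NULL 1, KO NULL 2 or WT NULL 1, Epyc without KO NULL 1, and Zbp1, Oas2, Irf7, Hormad1 and Sult4a1 in none of the 8 omissions. Mitochondrially encoded transcripts were lower at 3 of 13 (6 adjusted over the list alone; median -0.32; camera adjusted p = 1.33e-06, adjusted p = 0.5525 with an estimated correlation). Of 4 measured dendritic cell markers, 1 was higher in KO (3 adjusted over the list alone; median 1.01; camera adjusted p = 0.0272, adjusted p = 0.4551 with an estimated correlation; the call was lost with no filter and with a mean of at least 50). These were Fscn1, an actin bundling gene (log2 0.76, adjusted p = 0.0055), and, not past the threshold over all genes, Itgax (CD11c; 2.37, adjusted p = 0.0985) and Xcr1 (1.26, adjusted p = 0.1506), while Zbtb46 stood at -0.15 (adjusted p = 0.7448). Macrophage and monocyte markers were not called (0 of 15 passed; median 0.14; camera adjusted p = 0.2563). The NF-kB list was called by camera and kept its call in 16 of 16 settings. Its medians from the WT NULL mean were 0.388 and 0.562 in the KO NULL libraries. With an estimated correlation, 0 lists were called for KO in NULL virus.

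KO fibroblasts with IL-33 were also compared with WT NULL cells, a contrast that combines both changes. It held 1095 genes, 644 higher and 451 lower (293 and 173 by at least 2-fold). Il33 (log2 10.55, adjusted p = 0.0043), Hormad1, Epyc (22.4-fold), Dio2 (17.5-fold) and Mstn (17.4-fold) were the named genes with the largest rises, and Rgs5 (41.6-fold), Eln (35.5-fold), Erbb4 (23.2-fold), Sult4a1 (15.0-fold) and the polarity gene Crb2 (11.7-fold) those with the largest falls. Of 28 interferon genes, 18 were higher and 0 lower (23 higher adjusted over the list alone; median 0.95; camera adjusted p = 1.68e-18, adjusted p = 0.5318 with an estimated correlation), with Zbp1 9.48-fold higher. The count was 6004 and 6008 without the WT FL or WT M library, 108 and 106 without KO FL or KO M, 325 and 321 without KO NULL 1 or 2, and 96 and 106 without WT NULL 1 or 2. Rgs5 and Crb2 lost their calls without any 1 of the NULL or KO IL-33 libraries. Eln, Dio2 and Erbb4 lost theirs without KO FL, KO M or either WT NULL library, Epyc and Mstn without KO M, and Il33 without either WT NULL library.

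**Figure D3:**
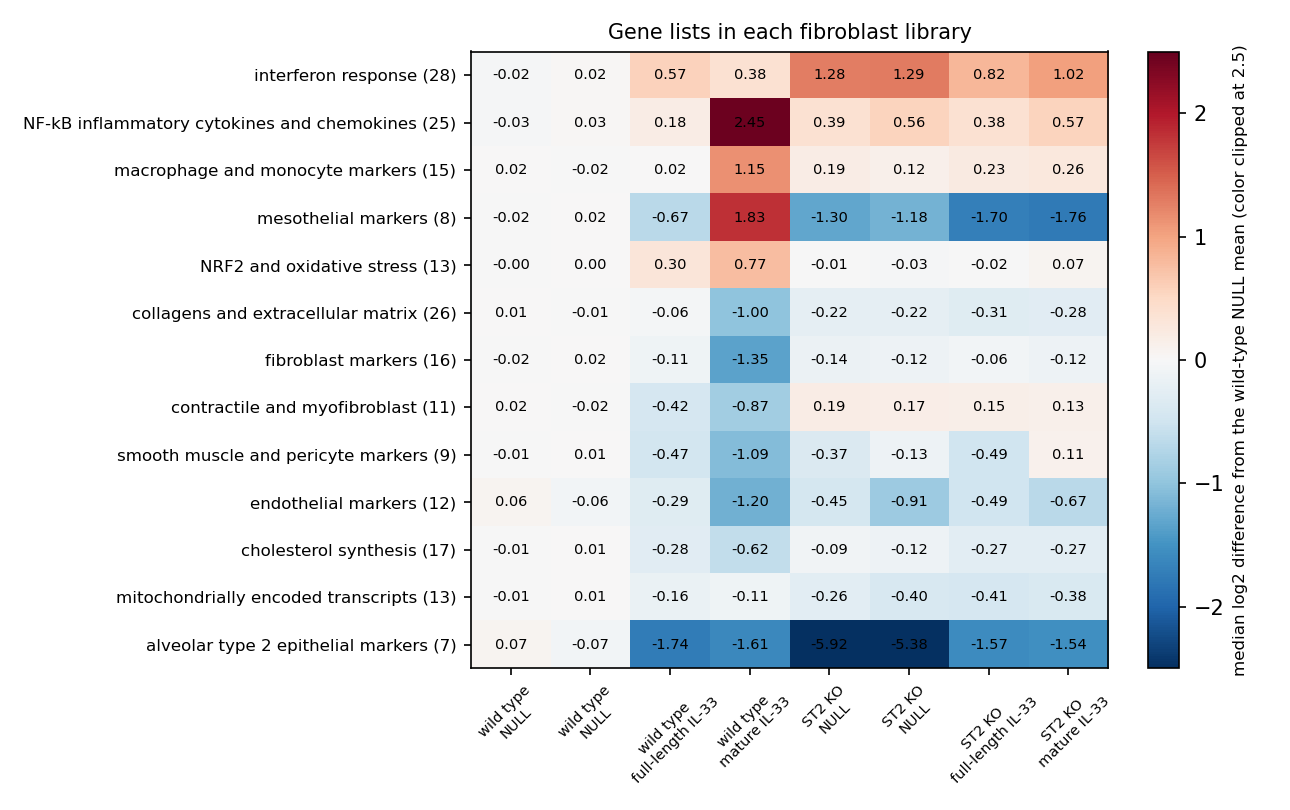
Median log2 difference from the WT NULL mean of 13 gene lists in each fibroblast library, with the colour scale clipped at 2.5.

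Full-length and mature IL-33 did not differ past the threshold at any gene when the difference was averaged over genotypes. The limma count was 0 of 15527, with 886 genes at an unadjusted p below 0.05 against 776 expected by chance; the spread taken from the NULL pairs gave 3160. The genes with the smallest p were the heat shock genes Hspa1a (log2 1.80 higher with FL, SE 0.22) and Hspa1b (1.29, SE 0.23), and Rhoq (0.55), with Rac2 (-1.16), St6gal1 (-0.70) and Oxnad1 (-0.73) in the other direction, each with adjusted p = 0.6110. Hspa1a was at 2081 normalized counts in KO FL and 881 in WT FL, against 317 to 516 in the other 6 libraries. Without the KO M library the count was 5052 and without the WT M library 2.

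Between the isoforms, camera called 11 of 33 lists. NF-kB dependent genes had a median of -1.27 (0 of 25 passed; camera adjusted p = 2.52e-09), collagens and matrix genes 0.55 (0 of 26; adjusted p = 4.30e-07), fibroblast markers 0.64 (0 of 16; adjusted p = 2.26e-05) and macrophage markers -0.59 (0 of 15; adjusted p = 2.46e-06). With an estimated correlation no list was called, with adjusted p = 0.5860 for each of these 4. Without the WT M library these 4 calls were lost, with adjusted p = 0.7741, 0.8551, 0.7114 and 0.8158. The glycolysis and hypoxia list (median 0.06, 0 of 19; adjusted p = 0.0277, adjusted p = 0.5860 with an estimated correlation) kept its call without the WT M library. It lost it without the KO M or WT FL library, with a mean of at least 50 and with quantile normalization (adjusted p up to 0.7696). The interferon response list was not called (0 of 28; adjusted p = 0.7676).

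Across 15526 genes (Il33 left out; genes are not independent replicates), the IL-33 response of WT cells was nearly unrelated to that of KO cells, with r = 0.020 and rho = 0.139. For FL alone r was 0.069 and for M alone -0.043. The KO effect in NULL virus and the IL-33 effect in WT, which share the WT NULL pair, had r = 0.505 and a covariance of 0.212. Simulations of unchanged groups with these shared controls gave 0.501 and 0.0787. They used the spread of the 4 groups, which includes the isoform difference. Sharing a control sets the simulated r by construction, so the likeness in r does not show that the shared controls explain the relation. The observed covariance was the larger. Of the 28 genes that rose with IL-33 in WT, 25 were among the 400 higher in KO NULL, and of the 13 that fell, 4 were among the 264 lower. The shared controls raise such overlaps, and the number they alone would give was not computed. The FL and M responses averaged over genotypes had r = 0.445 and a covariance of 0.0774 with shared controls. Simulations of unchanged groups with the spread of the NULL pairs gave a covariance of 0.021 and r = 0.328, again set by construction. With the NULL libraries split between the FL and M responses, r was 0.266 and 0.297.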

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

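The tests of scaling, cell types, sample labels, virus dose and gene position were chosen after the results were seen, and the other splits of the libraries were planned. The IL-33 effect in KO minus that in WT passed the threshold of its own test at 20 genes, of which 10 fell under the rule for naming. The difference was 8.92 for Sftpc, 7.17 for Sftpb, 2.18 for Ramp1, 1.38 for Popdc2 and 1.26 for Cspg4 on the log2 scale. It was -2.58 for Ly6a, -2.39 for Zbp1, -2.35 for Oas2, -2.08 for C4b and -1.72 for Igfbp3. The values for Sftpc and Sftpb rest on KO NULL libraries near 0. Each difference compares 2 IL-33 and 2 NULL libraries per genotype.

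The first pattern is the WT M library, which differed from the WT NULL pair at 7650 genes, with inflammatory, macrophage and mesothelial genes up and matrix genes down. Scaling as the cause is argued against by the count under quantile or TMM scaling, of which the value farthest from 7650 was 7689. That count covers all genes and does not test the matrix genes on their own. For IL-33 in WT, the collagen and fibroblast list calls were lost with quantile normalization. A lower share of fibroblasts as the whole cause would raise markers of all other cell types alike, but the macrophage list (median 1.15, median absolute deviation 0.237) and the endothelial list (-1.20, 1.21) were 2.35 apart. A KO sample under a WT label is argued against by 38 of 60 genes with separate levels in the genotypes, at which this library lay nearer to the WT mean, Hormad1 among them (0 against 1276 to 1434 normalized counts in KO), although its median position over 931 genes was 0.64 of the way from WT NULL to KO NULL (median absolute deviation 0.53). A response of WT cells to mature IL-33, or a culture that gained macrophages and mesothelial or other epithelial cells (airway list median 1.82), may each be the cause, and 1 library without a repeat leaves both open.

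The second pattern is the higher interferon genes of KO cells with NULL virus (median log2 1.29 over 28 genes). Scaling is argued against by the lowest median under the other scalings, 1.28, and more macrophages in KO cultures by their marker list, with a median of 0.145 (median absolute deviation 0.278). The 4 measured dendritic cell markers had a median of 1.01, with Fscn1 (14574 normalized counts against 8636) and Itgax (338 against 65.0) the most abundant. Of the class II genes that such cells express, Cd74 stood at -2.57 on the log2 scale (SE 0.757, not past the threshold over all genes). H2-Aa was listed at 0 in KO NULL against 26.3 and 21.7. These genes were chosen after their values were seen. The whole class II list (5 measured) had medians of 0.137 and 0.1 in the KO NULL libraries, so more dendritic cells are left open. A different virus dose and genotype cannot be told apart in the NULL libraries, which hold no vector transcript to measure; in the M pair the interferon genes were higher in KO by 0.77 where Il33 was lower (-1.62), and in the FL pair by 0.28 where Il33 was higher (0.86). Loss of ST2, virus dose in the NULL cells, more dendritic cells in KO cultures and variants linked to the strain of the KO mice may each contribute.

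The third pattern is 30 genes whose KO libraries all lay at least 4-fold above (23 genes) or below (7) all WT libraries, where the other 34 ways to split the libraries into 4 and 4 gave at most 2. Hormad1, Zhx2, Sult4a1 and Zfp979 are examples. DNA of the targeted strain around Il1rl1 as the cause of these genes is argued against by their positions: 30 of 30 lie outside 10 Mb of Il1rl1, with 0 of the 97 tested genes inside among them. On chromosome 1, which holds Il1rl1, lie 5 of the 30, and for those a longer linked segment is not excluded. Variants of another strain elsewhere in the genome may be a cause and cannot be told apart from the loss of ST2, since no reads were analysed; the 30 genes lie on 16 chromosomes, which decides nothing.

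Of the 35 ways to split the 8 libraries into 4 and 4, only the real genotype split called as many as 1853 genes (highest other 205). Most other splits put the genotype difference into the spread, which lowers their counts. The labels do not say whether the libraries of a genotype came from separate animals. A chance difference between the sources of the cells is therefore not excluded. For IL-33 averaged over genotypes, 7 of 35 splits, the real one included, called as many as the real 5. Among them was the split by genotype itself, with 1497 genes. A split that follows a known difference between samples does not measure chance. The splits therefore do not decide, and chance is not excluded. The highest other split called 3440; a count so far above 5 points to a structure of the samples, with the WT M library and 3 KO libraries on one side.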

How the results depend on the processing

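The comparisons of single IL-33 libraries, with each of their settings, were added after the results were seen, and the other settings were planned. Tests on whole reads with edgeR and DESeq2 were not run. No named gene reversed its direction where called. A list was counted as reversed only where it was called in both settings, and none was. Lists that changed direction and lost or gained a call are counted as lost or gained. Across the settings that kept all libraries, 8330 of 9115 values of named genes kept their side of the threshold (175 lost, 610 gained), as did 2337 of 2624 values of lists (205 lost, 82 gained). With 1 library left out, 7612 of 9288 values of named genes kept it (765 lost, 911 gained). For lists, 1918 of 2112 values did (98 lost, 96 gained). The interferon list kept its call in 16 of 16 settings with the preset correlation for IL-33 in WT, IL-33 in KO, the difference between genotypes, KO averaged, KO in NULL virus and KO with IL-33. With an estimated correlation, 1 list call was kept, the alveolar type 2 list for IL-33 in KO. Fry, which asks whether a list moves on balance, called 1 list for averaged IL-33, 8 for IL-33 in WT, 1 for IL-33 in KO, 3 for the difference between genotypes, 10 for KO averaged, 6 for KO in NULL virus, 8 for KO with IL-33 and 0 for FL against M, where camera called 13, 14, 6, 13, 8, 11, 13 and 11. The interferon list was called by fry in these comparisons except averaged IL-33 (adjusted p = 0.2571), IL-33 in KO (0.8449) and FL against M (0.9888). Taking the spread from the NULL pairs alone (6 groups) raised the counts: averaged IL-33 4241, IL-33 in WT 5814, IL-33 in KO 27, difference between genotypes 3188, KO averaged 6332, KO in NULL virus 5096, KO with IL-33 6171, and FL against M 3160. By construction, what left the spread was the isoform difference in the first 7 counts and the difference between genotypes in the responses to FL and M in the last. With the number of the NULL libraries as a replicate block the counts were, in the same order, 0, 10, 2, 1, 959, 261, 371 and 0. The numbers are not known to pair the libraries, and the NULL 1 minus NULL 2 differences in KO and WT had r = 0.023 across genes. An added 8 gave 1 for averaged IL-33 and 12 for the difference. No filter gave 2 for averaged IL-33, 683 for KO with IL-33, 732 for the KO FL library and 814 for the KO M library, and a mean of at least 50 gave 2 for averaged IL-33 and 3 for the KO M library; the cause was not tested. Leaving out 1 library gave 0 to 6238 for averaged IL-33, 0 to 7491 for IL-33 in WT, 0 to 8 for IL-33 in KO, 0 to 5604 for the difference, 552 to 6161 for KO averaged, 70 to 4998 for KO in NULL virus, 96 to 6008 for KO with IL-33 and 0 to 5052 for FL against M. For the single libraries it gave 438 to 984 (WT FL), 6928 to 7099 (WT M), 6 to 15 (KO FL) and 1 to 7 (KO M). The high values for the comparisons of groups came without the WT FL or WT M library, which takes the isoform difference in WT out of the spread. Either omission also left 1 library to stand for IL-33 in WT. For FL against M the high value came without the KO M library, which takes the difference between genotypes in the M response out of the spread. The 1853 genes of KO averaged were all kept without the WT FL or the WT M library. Scaling by TMM or quantiles moved no count of genes by over 1.5 times. The depth was 2.37e+07 to 3.97e+07 reads. Whether it limits genes with low values, such as Il1rl1 (18.3 and 106 in WT NULL), was not tested.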

Other observations

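The tests in the other parts that were chosen after the results were seen are named there, and the values given here were chosen after they were seen. Surfactant genes of alveolar type 2 cells were near 0 in the KO NULL pair and higher in the other 6 libraries for Sftpc and Sftpb. Sftpc was at 969 and 765 normalized counts in WT NULL, at 233 and 147 in WT with FL and M, at 162 and 156 in KO with FL and M, and at 1.36 and 0 in KO NULL. Sftpa1, which encodes surfactant protein A, followed with 115 and 30.8 in WT NULL, 8.0 and 1.29 in WT with FL and M, 8.9 and 16.7 in KO with FL and M, and 0 and 0.451 in KO NULL. The KO NULL libraries thus differed from the KO libraries with IL-33 in these genes, while the levels with IL-33 were alike in both genotypes for Sftpb (49.6 and 54.3 in WT, 55.8 and 57.3 in KO). Abca3, a lipid transporter gene on the same list, was at 1864 to 3114 in all 8 libraries.

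Il6, a cytokine gene of the NF-kB list, and Npnt, a fibroblast marker, also differed by genotype. Il6 was at 960 to 1053 normalized counts in KO and 454 to 615 in WT libraries (log2 0.97, adjusted p = 6.02e-04), and Npnt, which encodes the integrin ligand nephronectin, at 5405 to 7034 against 812 to 1712 (log2 2.25, adjusted p = 2.20e-04). Near Il1rl1 on chromosome 1, Il1rl2 (log2 0.69, adjusted p = 0.0046) and Il1r1 (0.51, adjusted p = 0.0193) were higher in KO and Map4k4 was lower (-0.38, adjusted p = 0.0107), among 12 neighbours with a median of 0.06. Of the tested genes within 10 Mb of Il1rl1, 13.4% were called for genotype, against 11.9% elsewhere.

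On a scale over 931 genes with 0 at the WT NULL mean and 1 at the KO NULL mean, the WT FL library had a median position of 0.30 and the WT M library 0.64. The KO FL library stood at 1.04 and the KO M library at 1, so their median genes lay at the KO NULL level. The NULL libraries define the scale and lie at its ends by construction. The genes were chosen as past the threshold and at least 2-fold apart between these NULL pairs, in a fit without the WT M library. Such a choice can by itself move other libraries off the ends, by an amount that was not computed.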
